A study of Mus musculus with 23 samples.

How the data were processed

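The deposited values number 1 for each of 45101 probe sets on 23 arrays, measured in medulloblastoma allografts of nude mice. Per the labels, the labelled cRNA was biotinylated, starting from at least 2.5 µg of RNA, and the authors processed the arrays with MAS5, whose version is not given. The deposited values are linear signal intensity, and the 2% trimmed mean was 150 on every array, so the authors had scaled each array to that mean. Detection calls and probe-level values are not used here. The study's design text names the Mouse Genome 430A 2.0 array, while 45101 probe sets are the layout of the larger Mouse 430 2.0 array. Across arrays the median signal ranged from 33.9 to 46.7, the 40th percentile from 18.7 to 28.6 and the log2 ratio of 3' to 5' actin probe sets from 0.84 to 1.83. Such values give no counting error.

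Samples were grouped by their description into vehicle (3 arrays, no stated time), 4 h vehicle (2), drug at 40 mg/kg for 4, 8, 24 and 48 h (3 each) and resistant at 40 and 160 mg/kg (3 each). All 23 columns were mapped. For 6 of the 12 short-term treated arrays another label says resistant, and the description was followed. Probe sets were named from the annotation supplied with the series: 34958 have 1 gene symbol, 932 several and 9211 none, and 0 symbols were changed through their Entrez identifier. The 64 control probe sets were left out, except that actin and Gapdh controls served as a measure of RNA integrity. Values were analysed as log2 of signal plus 16. A probe set was tested when it exceeded its array's 40th percentile on at least 2 arrays, which kept 35069 probe sets, 28330 of them with 1 symbol, covering 14980 genes.

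Differences were tested with limma 3.58.1 in R 4.3.3, with version 1.17.8 of the data.table package. A mean for each of the 8 groups was fitted in 1 model, with eBayes and its trend option (23.5 residual and prior degrees of freedom). P-values are two-sided and adjusted by Benjamini-Hochberg within each of the 11 comparisons, at a threshold of 0.05. Pooled over all groups, the fit lets groups of 2 or 3 arrays borrow the spread of the others. The resistant comparison weights its 2 dose groups equally. The 24 h and 48 h arrays were set against the vehicle arrays with no stated time, since no array is labelled as a vehicle of those times.

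Before the data were examined, the groups, comparisons, gene lists, the rule for named genes and the alternatives were fixed, except where the text says otherwise. The 32 lists were Hedgehog pathway targets, Hedgehog pathway components, granule neuron progenitor genes, neuronal differentiation, DNA replication and S phase, mitosis, PI3K and insulin-like growth factor signalling, receptor tyrosine kinase and MAPK feedback, immediate early genes, hypoxia and glycolysis, p53 and apoptosis, drug efflux transporters, Notch signalling, Wnt signalling, cholesterol synthesis, interferon response, ribosome biogenesis and Myc targets, unfolded protein and stress response, oxidative phosphorylation, cytoplasmic ribosomal proteins, and markers of endothelial cells, pericytes and smooth muscle, fibroblasts and matrix, macrophages and microglia, neutrophils, lymphocytes and natural killer cells, skeletal muscle, adipocytes, skin, astrocytes and glia, oligodendrocytes and Schwann cells, and erythroid cells. Lists with at least 5 measured genes were tested with camera at a preset inter-gene correlation of 0.01, with an estimated correlation and with fry, and each gene entered by the probe set with the highest mean log2 signal. Lists overlap: Hedgehog targets share 3 genes with Hedgehog components.

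Genes named in the text are Gli1, Ptch1, Hhip, Sfrp1, Gli2, Mycn, Ccnd1, Smo and Sufu in every comparison, then genes drawn from the 10 largest rises and 10 largest falls at 48 h, in resistant tumours and between these, or the 5 and 5 largest elsewhere, among called genes whose every test array lies beyond the control mean, and from the 4 called members with the smallest p of each list past camera. Among these, genes whose call did not rest on 1 array were preferred. Ccnd3, Pik3r3, Igf1r, Igf1, Abcb1a, Abcb1b, Abcg2, Inhbb and Ralb were chosen after their values were seen. Probe sets matching several transcripts have shared probes, and their values are uncertain. Other probe sets of a named gene were not always called. Some genes are not analysed here.

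Alternatives were offsets of 1 and 64, no filter, the 60th percentile, quantile normalization, eBayes without trend, only the compared arrays in the fit, all 5 vehicle arrays as control, the replicate number or the run of identifier numbers in the sample titles (3 runs) as a block, and leaving out each array in turn. The 4 h vehicle as control of the later times and array weights per group were added after the data were seen. Other splits of the same arrays were counted for comparisons of at least 3 arrays a side. The fit was tested on simulated data with 100 changed probe sets: at a log2 change of 1 it called 39% at 4 h and 68% in the resistant comparison, and at a change of 2 it called 92% and 98%. No arrays were identical, and arrays of a group correlated at 0.945 to 0.978. Gene order came from the GRCm38.p6 annotation. Figures were drawn with matplotlib 3.10.9, numpy 2.4.6 and pandas 2.3.3 in Python 3.11.15.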

Results

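Gene expression was measured in medulloblastoma tumours grown under the skin of nude mice. The tumours came from Ptch+/-HIC+/- mice, which lack 1 working copy of the Hedgehog receptor gene Ptch1, and the mice received vehicle or NVP-LDE225, an antagonist of the Hedgehog signal transducer Smoothened. The series holds 23 arrays in 8 groups. Vehicle was given to 3 tumours with no stated time and to 2 tumours collected at 4 h. Sensitive tumours were collected at 4, 8, 24 and 48 h after 40 mg/kg of the drug, with 3 arrays at each time. Resistant tumours treated at 40 mg/kg and at 160 mg/kg gave 3 arrays each, with no stated time since dosing. The highest signal per array ranged from 13784 to 24678, and the number of arrays limits precision. For 6 of the 12 short-term treated arrays, a label says resistant, but the description was followed. The labels do not say whether replicates are separate animals, so p-values measure the spread between these samples. A probe set is called at a limma adjusted p under 0.05 over 35069 tested probe sets. Changes are log2 differences of signal plus 16, which understates changes of genes with low signal, and signals are given as mean ± SD. In the plot of called probe sets by comparison, more were called at each later time, and fewer were called between resistant and vehicle tumours than between 48 h and vehicle tumours.

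**Figure D1:**
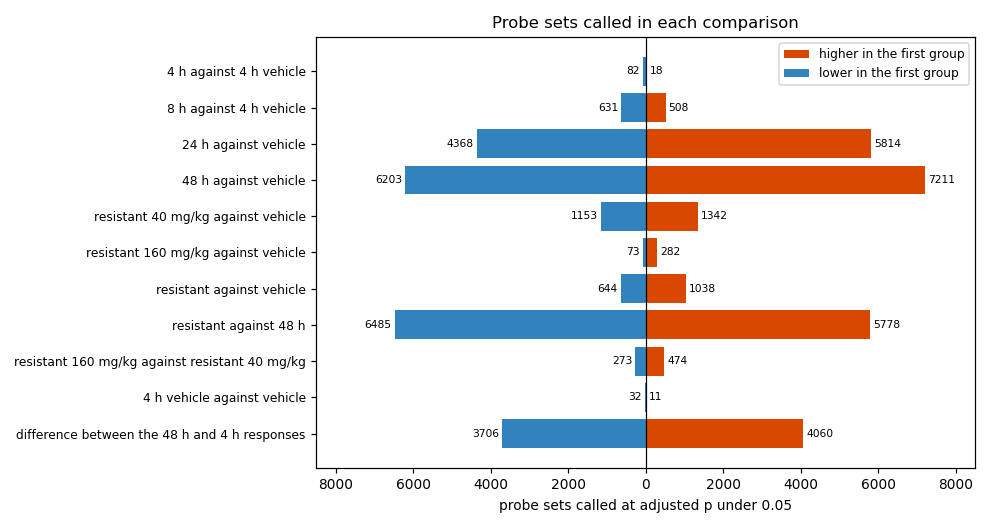
Bars give the number of probe sets called at an adjusted p under 0.05 (x axis) in each of the 11 comparisons (y axis), to the right when higher and to the left when lower in the group named first. For 48 h against vehicle the bars stand at 7211 higher and 6203 lower probe sets.

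The 4 h arrays were compared with the 4 h vehicle arrays to ask which genes respond first to the antagonist. Hedgehog target genes fell. Gli1, a transcription factor induced by the pathway and a standard readout of it, was 100.2 ± 19.99 (SD, n = 3) against 608 ± 129 (SD, n = 2) in vehicle, a log2 change of -2.42 (adjusted p = 0.0011). Ptch1, the Hedgehog receptor and a target of its own pathway, fell by 1.01 (adjusted p = 0.0026), Gli2, the main activator of the pathway, by 0.96 (adjusted p = 0.0024) and Ccnd1, cyclin D1, by 1.03 (adjusted p = 0.0013). Mycn, a growth-promoting transcription factor, changed by -0.71 (adjusted p = 0.018). Ptch1 and Mycn each had 1 of 3 probe sets called. Hhip, a Hedgehog-binding target gene, gave -1.03 (adjusted p = 0.56) and Sfrp1 -0.20 (adjusted p = 0.97). Smo gave 0.05 (adjusted p = 0.99, shared probes) and Sufu -0.43 (adjusted p = 0.5). Of the 17 measured Hedgehog pathway targets 5 fell, 0 rose and 12 were not called (0 higher and 7 lower adjusted over the list alone). The list fell as a group (median -0.31, camera adjusted p = 1.1e-10, and adjusted p = 0.00018 with an estimated correlation).

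Genes outside the pathway lists responded at 4 h as well. Sox18, an endothelial transcription factor, fell from 908 ± 7.28 to 171 ± 8.76 (log2 -2.30, adjusted p = 4.5e-05). Among 23 immediate early genes 2 fell and 0 rose (0 higher and 3 lower adjusted over the list alone). The AP-1 member Fosl2 fell from 626 ± 65.3 to 210 ± 56.7 (-1.53, adjusted p = 4.5e-05), and Egr1 changed by -1.24 (adjusted p = 0.0024). The list's camera adjusted p was 9e-04, and adjusted p = 0.41 with an estimated correlation. Of 23 granule neuron progenitor genes, the normal cell of origin of such tumours, 1 rose and 2 fell (7 higher and 3 lower adjusted over the list alone), with a camera adjusted p of 0.0024 and adjusted p = 0.29 with an estimated correlation. The 41 DNA replication genes had a median of -0.25 with 0 called (0 higher and 3 lower adjusted over the list alone), a camera adjusted p of 1.1e-08 and adjusted p = 0.48 with an estimated correlation. None of the 46 mitosis genes was called (0 adjusted over the list alone, median 0.07, camera adjusted p = 0.5).

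Of the 32 lists 7 passed camera at 4 h, and 1 of them with an estimated correlation. In all 18 probe sets were higher and 82 lower at 4 h, and 2316 had an unadjusted p under 0.05. The count fell to 49 without treated replicate 2, 66 without treated replicate 3, 30 without vehicle replicate 1 and 36 without vehicle replicate 2, where the lone vehicle array is assumed to vary like the other groups. Without vehicle replicate 1 the adjusted p was 0.13 for Ptch1, 0.13 for Gli2, 0.25 for Mycn and 0.055 for Egr1. With the identifier run as a block it was 0.17 for Ptch1 and 0.18 for Gli2. Without vehicle replicate 2 it was 0.056 for Gli1 (0.24 with an offset of 1), 0.06 for Ccnd1, 0.17 for Mycn and 0.069 for Egr1, and for Mycn it was 0.066 without treated replicate 2 and 0.12 without treated replicate 3.

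The 8 h arrays, set against the same 4 h vehicle arrays since none is labelled as an 8 h vehicle, asked what follows the first response. DNA replication genes fell at 8 h, and none of the mitosis genes was called. Of the 41 DNA replication and S phase genes 34 fell, 0 rose and 7 were not called (0 higher and 39 lower adjusted over the list alone), with a median of -1.10, a camera adjusted p of 8.4e-56 and adjusted p = 0.0092 with an estimated correlation. Cdt1, which licenses replication origins, fell from 1972 ± 343 (n = 2) to 435 ± 12.9 (n = 3), a change of -2.13 (adjusted p = 2.4e-08). Cdc6, its partner, changed by -2.50 (adjusted p = 1.3e-07), and the helicase subunit Mcm4 fell from 1755 ± 168 to 475 ± 57.6 (-1.85, adjusted p = 1.1e-06). Mitosis had 0 of 46 genes called (0 adjusted over the list alone) and a median of -0.11 (camera adjusted p = 0.097).

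Hedgehog targets were below vehicle at 8 h too. Gli1 was 10.5 ± 11.2 (SD, n = 3), near the background of the arrays (-4.62, adjusted p = 1.7e-08), and Ptch1 was 731 ± 51.9 (-1.59, adjusted p = 1.2e-06). Gli2 was 465 ± 36.0 (-1.53, adjusted p = 8.4e-07). Ccnd1 was 1760 ± 106 (-1.33, adjusted p = 6e-06). Hhip fell by 1.97 (adjusted p = 0.0037, and 0.08 without vehicle replicate 1). Mycn gave -0.48 (adjusted p = 0.055), Sfrp1 -0.32 (adjusted p = 0.74), Smo -0.08 (adjusted p = 0.87, shared probes) and Sufu -0.45 (adjusted p = 0.13). Of the 17 targets 6 fell and 0 rose (0 higher and 8 lower adjusted over the list alone), with a median of -0.47, a camera adjusted p of 9e-11 and adjusted p = 2e-04 with an estimated correlation.

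Some members of other lists were also called at 8 h. Granule neuron progenitor genes had 7 risen and 2 fallen of 23 (9 higher and 3 lower adjusted over the list alone, camera adjusted p = 0.0018, adjusted p = 0.14 with an estimated correlation). Sox4 rose from 2627 ± 52.1 to 5088 ± 328 (0.95, adjusted p = 0.00055). Of 40 neuronal differentiation genes 2 rose and 0 fell (5 higher and 0 lower adjusted over the list alone, camera adjusted p = 0.0024, adjusted p = 0.6 with an estimated correlation), among them Cbln1, a synapse organiser of granule neurons, at 1.33 (adjusted p = 8.6e-05). Of 23 immediate early genes 4 fell (0 higher and 4 lower adjusted over the list alone, camera adjusted p = 0.0013, adjusted p = 0.3 with an estimated correlation). Egr1 was at -2.03 (adjusted p = 5.8e-07). Hexokinase Hk2 fell from 1105 ± 125 to 246 ± 20.6 (-2.10, adjusted p = 6e-06) in a hypoxia and glycolysis list of 28 with 2 fallen (1 higher and 2 lower adjusted over the list alone, camera adjusted p = 0.0032, adjusted p = 0.75 with an estimated correlation). The largest rises included Cemip, a hyaluronan-degrading protein, from 64.8 ± 5.73 to 450 ± 32.6 (2.53, adjusted p = 6.9e-06). Of the 32 lists 9 passed camera at 8 h, and 2 of them with an estimated correlation. In all 508 probe sets were higher and 631 lower. The count was 713, 734 and 714 without treated replicates 1, 2 and 3, and 601 and 449 without vehicle replicates 1 and 2. It was 545 with the identifier run as a block, 1733 with only the arrays compared in the fit and 2366 with all 5 vehicle arrays as control.

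The 24 h arrays, against the vehicle arrays with no stated time, asked how far the programme had moved after a day. Mitosis genes had fallen together by then. All 46 measured mitosis genes fell (0 higher and 46 lower adjusted over the list alone), with a median of -3.20, a camera adjusted p of 3e-56 and adjusted p = 0.022 with an estimated correlation. Mki67, the proliferation antigen, fell from 4810 ± 66.7 (SD, n = 3) to 346 ± 36.6 (SD, n = 3), a change of -3.74 (adjusted p = 7e-14), and Top2a, topoisomerase II alpha, changed by -3.83. DNA replication had 39 of 41 genes fallen (0 higher and 40 lower adjusted over the list alone, median -2.23, camera adjusted p = 4.8e-43, adjusted p = 0.022 with an estimated correlation). Uhrf1, which maintains DNA methylation in S phase, went from 1199 ± 159 to 88.4 ± 7.06 (-3.53). Ribosome biogenesis had 25 of 31 fallen (0 higher and 26 lower adjusted over the list alone, median -0.60, camera adjusted p = 6.9e-13, adjusted p = 0.022 with an estimated correlation), including nucleolin, Ncl, at -0.95.

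Hedgehog targets were low at 24 h, with 12 targets fallen and 3 risen of 17 (3 higher and 12 lower adjusted over the list alone, median -1.10, camera adjusted p = 2.3e-06, adjusted p = 0.0054 with an estimated correlation). Gli1 was 20.4 ± 24.1 against 679 ± 42.2 in vehicle (n = 3 each, -4.46, adjusted p = 1.1e-10) and Ptch1 372 ± 23.2 against 2713 ± 174 (-2.81, adjusted p = 9.1e-13). Gli2 was 378 ± 8.95 against 1298 ± 114 (-1.74, adjusted p = 7.8e-10). Ccnd1 was 892 ± 46.2 against 3741 ± 220 (-2.05, adjusted p = 4e-11). Hhip was 10.7 ± 2.91 against 211 ± 27.0 (-3.08, adjusted p = 2.7e-07). Mycn fell by 0.48 (adjusted p = 0.0044), and Fst, follistatin, from 892 ± 79.3 to 117 ± 16.5 (-2.77, and -1.72 against the 4 h vehicle). Sfrp1, a secreted Wnt antagonist, went the other way at 0.77 (adjusted p = 0.034). Its adjusted p was 0.074, 0.097 and 0.058 without 24 h replicates 1, 2 and 3, and 0.099 and 0.082 without vehicle replicates 1 and 2. Smo gave -0.17 (adjusted p = 0.32, shared probes) and Sufu -0.16 (adjusted p = 0.41).

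Neuronal genes rose at 24 h. Of 40 neuronal differentiation genes 29 rose and 2 fell (29 higher and 2 lower adjusted over the list alone), with a median of 1.29, a camera adjusted p of 5.7e-09 and adjusted p = 0.17 with an estimated correlation. Neurod1, a transcription factor of granule neuron differentiation, rose from 305 ± 27.7 to 3214 ± 457 (3.33, adjusted p = 3.1e-09), and Dcx, doublecortin of migrating young neurons, from 36.1 ± 9.49 to 923 ± 47.3 (4.19, adjusted p = 3.1e-07, and 2.55 against the 4 h vehicle). Granule neuron progenitor genes had 13 risen and 3 fallen of 23 (14 higher and 4 lower adjusted over the list alone, median 0.50, camera adjusted p = 0.011, adjusted p = 0.2 with an estimated correlation). Among the largest falls was Nptx1, neuronal pentraxin, from 4807 ± 236 to 72.2 ± 10.8 (-5.78, adjusted p = 3.6e-18).

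Cholesterol and glycolysis genes fell at 24 h, though neither list kept its call with an estimated correlation. Cholesterol synthesis had 13 of 20 fallen and 1 risen (2 higher and 14 lower adjusted over the list alone, median -0.66, camera adjusted p = 1.3e-06, adjusted p = 0.17 with an estimated correlation). Hypoxia and glycolysis had 12 fallen and 2 risen of 28 (2 higher and 14 lower adjusted over the list alone, camera adjusted p = 0.0032, adjusted p = 0.54 with an estimated correlation). Of the 32 lists 15 passed camera at 24 h, and 4 of them with an estimated correlation.

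Markers of other tissues and of RNA quality also differed at 24 h. Of 20 skeletal muscle markers 17 rose (19 higher and 0 lower adjusted over the list alone, median 2.91, camera adjusted p = 0.00041, adjusted p = 0.54 with an estimated correlation). Vehicle replicate 2 was itself at 2.60 and the other vehicle arrays at -1.21 and -1.26 around their mean. Myh1, a fast muscle myosin, gave 2405 ± 609 against 494 ± 854 (4.97, adjusted p = 0.016), with an adjusted p of 0.097 without vehicle replicate 1 and 0.096 without vehicle replicate 3, and 0.44 against the 4 h vehicle. The log2 ratio of 3' to 5' actin probe sets, a measure of RNA integrity, was 1.65 ± 0.22 at 24 h against 1.04 ± 0.04 in vehicle (SD, n = 3 each), so the cell cycle and neuronal changes at 24 h coincided with it. Fibroblast and matrix markers had 17 risen and 2 fallen of 28 (19 higher and 2 lower adjusted over the list alone, median 1.24, camera adjusted p = 0.0022). Endothelial markers had 10 risen and 1 fallen of 19 (10 higher and 1 lower adjusted over the list alone, median 0.84, camera adjusted p = 0.019) and macrophage markers 13 risen and 0 fallen of 25 (14 higher and 0 lower adjusted over the list alone, median 0.82, camera adjusted p = 0.00038). For these 3 lists adjusted p = 0.54 with an estimated correlation. In all 5814 probe sets were higher and 4368 lower at 24 h. The median change of all genes was 0.10 on the deposited scale and 0.05 after quantile normalization. Against the 4 h vehicle arrays, a control chosen after the data were seen, 7693 probe sets were called, 6394 of them called in the same direction in both comparisons.

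The 48 h arrays, against the same vehicle arrays, asked what the longest short-term treatment did. Ptch1, Gli2 and Ccnd1 had their lowest means of the 4 times. Gli1 was 12.3 ± 7.37 (SD, n = 3, -4.65, adjusted p = 3.6e-11) and Ptch1 257 ± 42.6 (-3.33, adjusted p = 2.6e-14). Gli2 was 111 ± 12.6 (-3.37, adjusted p = 8.6e-15). Ccnd1 was 294 ± 47.6 (-3.61, adjusted p = 2.7e-15). Mycn was 399 ± 64.4 (-1.51, adjusted p = 8.9e-10). Hhip was 13.2 ± 10.8 (-3.02, adjusted p = 1.8e-07). Smo fell by 0.92 (adjusted p = 9.9e-07, shared probes), while Sfrp1 gave 0.21 (adjusted p = 0.59) and Sufu -0.15 (adjusted p = 0.45). Of 17 targets 13 fell and 1 rose (1 higher and 13 lower adjusted over the list alone, median -1.51, camera adjusted p = 1.6e-07, adjusted p = 0.0023 with an estimated correlation). The plot of Hedgehog target genes on each array shows the fall over time and the levels in resistant tumours.

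**Figure D2:**
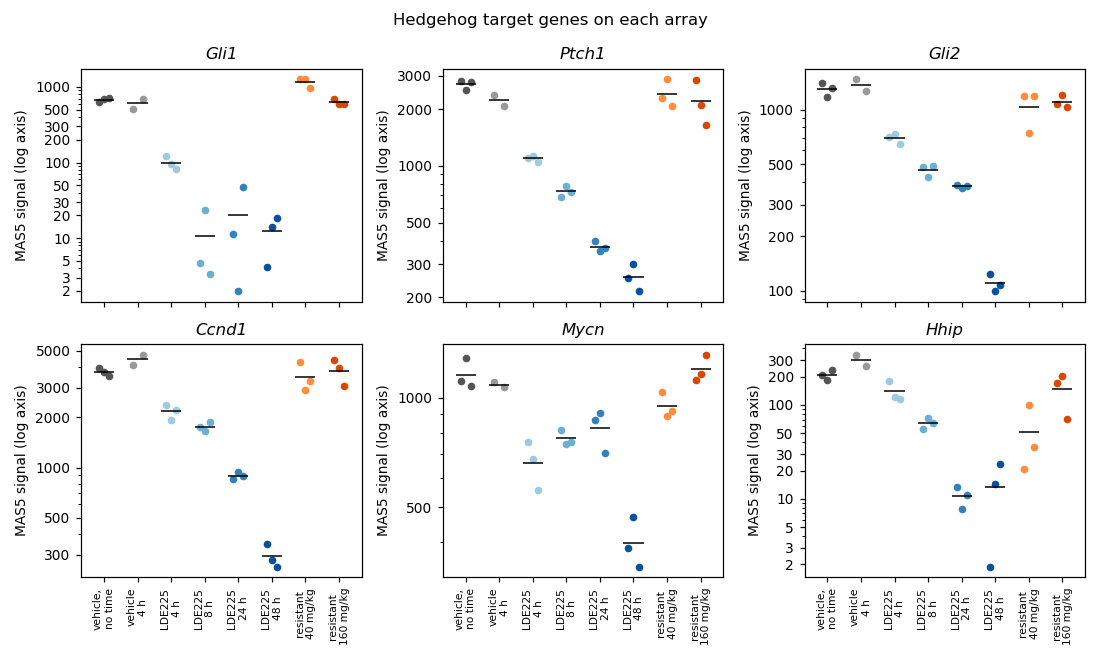
Each panel plots the MAS5 signal (y axis, log scale) of 1 Hedgehog gene on each of the 23 arrays (points) in the 8 groups (x axis), with black lines at group means. Mean Ptch1 goes from 2713 in vehicle to 257 at 48 h, and is 2420 and 2196 in resistant tumours at 40 and 160 mg/kg.

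Proliferation genes were low at 48 h. All 41 DNA replication genes fell (0 higher and 41 lower adjusted over the list alone, median -2.23, camera adjusted p = 7.5e-30, adjusted p = 0.07 with an estimated correlation). Of 46 mitosis genes 45 fell (0 higher and 45 lower adjusted over the list alone, median -2.79, camera adjusted p = 9.2e-33, adjusted p = 0.082 with an estimated correlation). Mki67 was at 573 ± 139 (-3.07, adjusted p = 1.3e-12). Ribosome biogenesis had 30 of 31 fallen (0 higher and 30 lower adjusted over the list alone, median -1.12, camera adjusted p = 7.9e-17, adjusted p = 0.015 with an estimated correlation). Cytoplasmic ribosomal proteins had 19 of 26 fallen (0 higher and 23 lower adjusted over the list alone, median -0.31, camera adjusted p = 9.4e-06, adjusted p = 0.33 with an estimated correlation), with a median of -0.13 (camera adjusted p = 0.032) against the 4 h vehicle.

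Neuronal genes were among the largest rises at 48 h. Chgb, chromogranin B of secretory granules, rose from 69.7 ± 13.3 to 7236 ± 135 (6.41, adjusted p = 1.4e-08), Slc17a6, a vesicular glutamate transporter, from 6.47 ± 1.55 to 1467 ± 72.2 (6.05, adjusted p = 7.4e-14) and Stmn2, a growth cone protein, from 6.90 ± 4.93 to 1358 ± 71.8 (5.93, adjusted p = 1.8e-12). The scavenger receptor Cd36, not neuronal, rose by 5.35, and against the 4 h vehicle by 5.75, beside 5.59, 5.60 and 5.48 for Chgb, Slc17a6 and Stmn2. Of 40 neuronal differentiation genes 29 rose and 1 fell (31 higher and 1 lower adjusted over the list alone). The median was 1.56 (camera adjusted p = 4.6e-08, adjusted p = 0.2 with an estimated correlation), or 1.09 against the 4 h vehicle. Neurod1 was at 6435 ± 204 (4.33) and Dcx at 1609 ± 14.6 (4.98, and 3.34 against the 4 h vehicle). Among the largest falls were the calcium-binding S100b, from 916 ± 184 to 3.03 ± 0.723 (-5.60, adjusted p = 5.1e-11), Nptx1 to 116 ± 35.8 (-5.23, adjusted p = 3.6e-17) and Wnt4 from 1604 ± 142 to 45.4 ± 26.5 (-4.80, adjusted p = 3.7e-12). Ccdc138 gave -5.80 (adjusted p = 2.1e-06), but it differs between the vehicle sets and gave -0.08 (adjusted p = 0.96) against the 4 h vehicle.

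Markers of non-tumour cells rose alongside these groups at 48 h. All 25 macrophage and microglia markers rose (25 higher and 0 lower adjusted over the list alone, median 3.50, camera adjusted p = 6.3e-17, adjusted p = 0.15 with an estimated correlation). Cd68, a lysosomal protein of phagocytes, rose from 128 ± 21.7 to 3072 ± 848 (4.40, adjusted p = 3.6e-12). Clec7a, the receptor dectin-1, rose from 51.3 ± 18.6 to 1924 ± 472 (4.86, adjusted p = 4.2e-12). Fibroblast and matrix markers had 25 risen and 1 fallen of 28 (25 higher and 1 lower adjusted over the list alone, median 2.23, camera adjusted p = 4.6e-08, adjusted p = 0.3 with an estimated correlation). Endothelial markers had 17 risen and 1 fallen of 19 (17 higher and 1 lower adjusted over the list alone, median 1.44, camera adjusted p = 0.00013, adjusted p = 0.33 with an estimated correlation). Neutrophil markers had 7 of 10 risen (7 higher and 0 lower adjusted over the list alone, camera adjusted p = 0.025, adjusted p = 0.15 with an estimated correlation). Adipocyte markers had 7 of 12 risen (10 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.027, adjusted p = 0.37 with an estimated correlation). Against the 4 h vehicle their camera adjusted p was 0.071. Interferon response genes had 25 risen and 1 fallen of 27 (25 higher and 1 lower adjusted over the list alone, median 1.53, camera adjusted p = 5.4e-07, adjusted p = 0.25 with an estimated correlation).

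Further lists passed camera at 48 h, none of them with an estimated correlation. Cholesterol synthesis had 15 fallen and 1 risen of 20 (1 higher and 15 lower adjusted over the list alone, median -1.08, camera adjusted p = 4e-06, adjusted p = 0.2 with an estimated correlation). Drug efflux transporters had 11 risen and 2 fallen of 17 (14 higher and 2 lower adjusted over the list alone, median 1.03, camera adjusted p = 0.00024, adjusted p = 0.074 with an estimated correlation). The risen members included the cholesterol exporters Abca1, from 800 ± 98.7 to 6348 ± 426 (2.97), and Abcg1 (3.02), which are known for lipid transport rather than drug transport. The unfolded protein response had 16 fallen and 2 risen of 26 (3 higher and 16 lower adjusted over the list alone, median -0.48, camera adjusted p = 0.0014, adjusted p = 0.27 with an estimated correlation). Heme oxygenase, Hmox1, was among the risen at 4.14. Hypoxia and glycolysis had 14 fallen and 5 risen of 28 (5 higher and 15 lower adjusted over the list alone, median -0.73, camera adjusted p = 0.02, adjusted p = 0.53 with an estimated correlation). Oxidative phosphorylation had 14 fallen and 2 risen of 41 (2 higher and 14 lower adjusted over the list alone, median -0.17, camera adjusted p = 0.0091, adjusted p = 0.43 with an estimated correlation). Its median was -0.06 (camera adjusted p = 0.18) against the 4 h vehicle and -0.05 (camera adjusted p = 0.43) after quantile normalization. In all 7211 probe sets were higher and 6203 lower, but 6300 and 7054 after quantile normalization, so which direction has more depends on the scaling. Against the 4 h vehicle, a control chosen after the data were seen, 11761 were called, 10227 of them called in the same direction in both comparisons, and Gli1 gave -4.48, Ptch1 -3.05 and the macrophage list a median of 3.96.

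**Figure D3:**
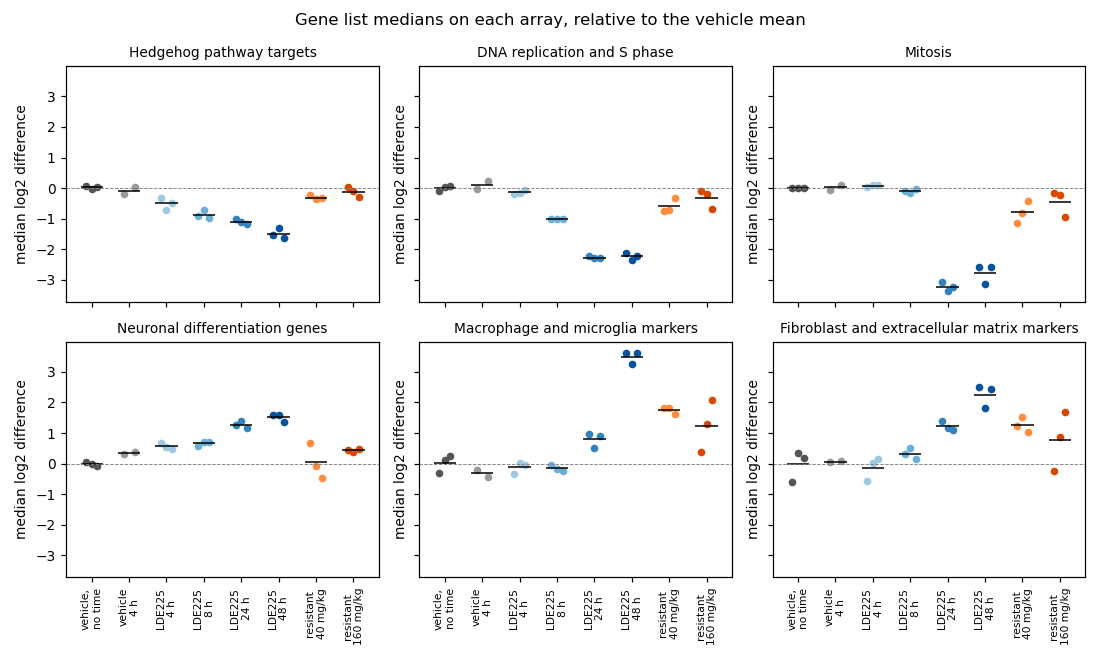
Each panel plots, for 1 gene list, the median log2 difference from the vehicle mean over its genes (y axis) on each of the 23 arrays (points) in the 8 groups (x axis), with black lines for group means and a dashed line for no difference. The macrophage panel runs from 3.25 to 3.63 on the 48 h arrays.

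The difference between the 48 h response and the 4 h response asked which changes came late. The 48 h arrays were set against the vehicle with no stated time and the 4 h arrays against the 4 h vehicle. Ptch1 fell by 2.32 more at 48 h than at 4 h (adjusted p = 7.1e-08), Gli2 by 2.41 (adjusted p = 1.7e-08), Ccnd1 by 2.58 (adjusted p = 5.9e-09) and Gli1 by 2.23 (adjusted p = 0.0011). Stmn2 rose by 6.03 more (adjusted p = 9.8e-09) and Slc17a6 by 6 more (adjusted p = 1.3e-09). S100b was at -4.52 (adjusted p = 3.9e-06). Sfrp1 gave 0.41 (adjusted p = 0.54) and Sufu 0.28 (adjusted p = 0.38). Of 32 lists 17 passed camera and 5 of them also with an estimated correlation. Hedgehog targets changed (1 higher and 11 lower of 17, also 1 and 11 adjusted over the list alone, adjusted p = 0.011 with an estimated correlation), and so did DNA replication (0 higher and 39 lower of 41, 40 lower adjusted over the list alone, adjusted p = 0.048 with an estimated correlation). Mitosis (45 lower of 46, also 45 adjusted over the list alone, adjusted p = 0.048 with an estimated correlation), drug efflux (8 higher of 17, 9 adjusted over the list alone, adjusted p = 0.048 with an estimated correlation) and ribosome biogenesis (24 lower of 31, 29 adjusted over the list alone, adjusted p = 0.017 with an estimated correlation) were the others. In all 4060 probe sets were higher and 3706 lower (3540 and 4047 after quantile normalization).

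Resistant tumours at 40 mg/kg were compared with vehicle tumours to ask whether Hedgehog output or other genes differed. Most core pathway genes were not called. Gli1 was 1165 ± 172 (SD, n = 3) against 679 ± 42.2 (0.76, adjusted p = 0.17), and its adjusted p was 0.011 with only the arrays compared in the fit and 0.0068 with an offset of 64. Ptch1 was 2420 ± 417 (-0.18, adjusted p = 0.58). Gli2 was 1042 ± 260 (-0.34, adjusted p = 0.15). Ccnd1 was 3509 ± 731 (-0.11, adjusted p = 0.73). Mycn was 951 ± 79.5 (-0.28, adjusted p = 0.21). Smo was 489 ± 11.3 (-0.27, adjusted p = 0.2, shared probes). Sufu was 308 ± 38.0 (0.04, adjusted p = 0.93). Hhip fell from 211 ± 27.0 to 52.2 ± 42.5 (-1.90, adjusted p = 0.0013) and Sfrp1 from 911 ± 91.4 to 314 ± 163 (-1.60, adjusted p = 0.00063). The cell cycle kinase Cdk6 fell by 1.38 (adjusted p = 7.5e-05) and Gas1, a Hedgehog co-receptor, from 1034 ± 131 to 595 ± 153 (-0.81, adjusted p = 0.0028). Of 17 targets 5 fell and 1 rose (3 higher and 11 lower adjusted over the list alone, median -0.34, camera adjusted p = 0.00018, adjusted p = 0.037 with an estimated correlation).

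Macrophage markers were higher in tumours resistant at 40 mg/kg, with 21 of 25 risen (23 higher and 0 lower adjusted over the list alone, median 1.77, camera adjusted p = 9.2e-26, adjusted p = 0.11 with an estimated correlation). Among the largest rises were Slc40a1, the iron exporter ferroportin, from 129 ± 41.7 to 1465 ± 526 (3.32, adjusted p = 2.1e-06) and Hmox1 from 95.3 ± 26.2 to 1104 ± 592 (3.23, adjusted p = 0.00013). Fibroblast and matrix markers had 15 risen and 1 fallen of 28 (21 higher and 1 lower adjusted over the list alone, camera adjusted p = 1.3e-10, adjusted p = 0.29 with an estimated correlation). Pericyte markers had 4 of 13 risen (5 higher adjusted over the list alone, camera adjusted p = 0.0027, adjusted p = 0.4 with an estimated correlation). Endothelial markers had 2 risen and 1 fallen of 19 (6 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.002, adjusted p = 0.5 with an estimated correlation) and neutrophil markers 5 of 10 risen (6 higher adjusted over the list alone, camera adjusted p = 0.009, adjusted p = 0.11 with an estimated correlation).

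Proliferation genes were lower at 40 mg/kg than in vehicle. Mitosis had 36 of 46 fallen (0 higher and 43 lower adjusted over the list alone, median -0.80, camera adjusted p = 9.2e-26, adjusted p = 0.11 with an estimated correlation). The checkpoint gene Mad2l1 went from 1693 ± 158 to 816 ± 198 (-1.06, adjusted p = 0.00061). DNA replication had 20 of 41 fallen (0 higher and 34 lower adjusted over the list alone, median -0.57, camera adjusted p = 2.1e-18, adjusted p = 0.11 with an estimated correlation). Hypoxia and glycolysis had 7 of 28 fallen (1 higher and 14 lower adjusted over the list alone, camera adjusted p = 1.1e-06, adjusted p = 0.37 with an estimated correlation). Cholesterol synthesis had 6 of 20 fallen (0 higher and 12 lower adjusted over the list alone, camera adjusted p = 2.6e-07, adjusted p = 0.13 with an estimated correlation), and ribosome biogenesis 6 of 31 (0 higher and 11 lower adjusted over the list alone, camera adjusted p = 1.5e-07, adjusted p = 0.11 with an estimated correlation). Drug efflux transporters had 6 of 17 risen (6 higher adjusted over the list alone, camera adjusted p = 0.00019, adjusted p = 0.11 with an estimated correlation). Abca1 was at 2703 ± 310 (1.74, adjusted p = 8.8e-05). Of the 32 lists 16 passed camera at 40 mg/kg, and 1 of them with an estimated correlation.

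Among the largest falls at 40 mg/kg, the matrix protein Spon2 went from 527 ± 135 to 43.6 ± 26.7 (-3.24, adjusted p = 4.3e-09) and the guidance cue Sema3e from 498 ± 138 to 66.0 ± 56.3 (-3.02, adjusted p = 4e-05). Nexmif, a neuronal gene, rose from 3.47 ± 1.35 to 208 ± 32 (3.52, adjusted p = 1.1e-10), and it also differs between the vehicle sets by 1.25. Cyclin D3, Ccnd3, chosen after its values were seen, rose from 409 ± 32.2 to 1498 ± 512 (1.78, adjusted p = 1e-06). In all 1342 probe sets were higher and 1153 lower, with 1468 in total without vehicle replicate 1 and 1658 without vehicle replicate 3. With only these arrays in the fit 1294 were called, 1227 of them among the 2495.

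Resistant tumours at 160 mg/kg, against vehicle, asked the same of the higher dose. None of the core pathway genes was called, with means of 633 ± 60.9 (SD, n = 3) for Gli1 (-0.10, adjusted p = 0.93), 2196 ± 598 for Ptch1 (-0.34, adjusted p = 0.31, and 0.031 without 160 mg/kg replicate 1 at -0.54), 1110 ± 92.6 for Gli2 (-0.22, adjusted p = 0.51) and 3813 ± 682 for Ccnd1 (0.01, adjusted p = 0.98). Mycn gave 0.05 (adjusted p = 0.9), Hhip -0.57 (adjusted p = 0.5), Sfrp1 -0.07 (adjusted p = 0.95), Smo -0.37 (adjusted p = 0.14, shared probes) and Sufu 0.38 (adjusted p = 0.2). None of the 17 Hedgehog targets was called (1 higher and 1 lower adjusted over the list alone, median -0.27, camera adjusted p = 0.027, adjusted p = 0.24 with an estimated correlation). Macrophage markers had 12 of 25 risen (21 higher and 0 lower adjusted over the list alone, median 1.19, camera adjusted p = 5.2e-21, adjusted p = 0.19 with an estimated correlation). Cd68 went from 128 ± 21.7 to 422 ± 241 (1.46, adjusted p = 0.0057). Alas2, the first enzyme of heme synthesis in red cells, rose from 17.3 ± 15.4 to 379 ± 272 (3.32, adjusted p = 0.0035) and Slc40a1 to 1142 ± 780 (2.82, adjusted p = 0.00021). Erythroid and blood markers had 1 of 5 risen (2 higher adjusted over the list alone, camera adjusted p = 0.018, adjusted p = 0.26 with an estimated correlation). Sbspon fell from 507 ± 109 to 147 ± 53.4 (-1.72, adjusted p = 0.0023, and 0.096 with all 5 vehicle arrays as control).

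Neuronal genes had 3 of 40 risen at 160 mg/kg (13 higher and 0 lower adjusted over the list alone, median 0.40, camera adjusted p = 5.9e-07, adjusted p = 0.26 with an estimated correlation). Neurod1 was 967 ± 522 (1.5, adjusted p = 0.011), and its adjusted p was 0.1 without 160 mg/kg replicate 3. Mitosis had 1 of 46 fallen (0 higher and 4 lower adjusted over the list alone, median -0.45, camera adjusted p = 9.2e-15, adjusted p = 0.26 with an estimated correlation). None of 41 DNA replication genes was called (0 adjusted over the list alone, median -0.29, camera adjusted p = 2.2e-09, adjusted p = 0.28 with an estimated correlation). Drug efflux transporters had 2 of 17 risen (5 higher adjusted over the list alone, median 0.54, camera adjusted p = 1.4e-05, adjusted p = 0.091 with an estimated correlation). Of 32 lists 17 passed camera and 0 with an estimated correlation. In all 282 probe sets were higher and 73 lower. The total was 45 without 160 mg/kg replicate 3, 950 without replicate 1, and 86, 170 and 178 without vehicle replicates 1, 2 and 3. With only these arrays in the fit 8 were called, 7 of them among the 355, and the adjusted p was 0.1 for Alas2, 0.067 for Slc40a1, 0.067 for Sbspon, 0.19 for Cd68 and 0.13 for Neurod1. That fit has fewer arrays and only the spread of these groups, and with array weights per group 279 of the 355 stayed called.

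The equally weighted mean of both resistant groups was compared with vehicle. Gli1 was 899 ± 313 (SD, n = 6, 0.33, adjusted p = 0.58) and Ptch1 2308 ± 477 (-0.26, adjusted p = 0.29). Gli2 was 1076 ± 179 (-0.28, adjusted p = 0.2). Ccnd1 was 3661 ± 654 (-0.05, adjusted p = 0.88). Mycn was 1076 ± 159 (-0.11, adjusted p = 0.64). Smo was 472 ± 36.1 (-0.32, adjusted p = 0.074, shared probes, and 0.045 without 160 mg/kg replicate 2) and Sufu 353 ± 79.6 (0.21, adjusted p = 0.38). A p that misses the threshold does not show that these levels were equal. Hhip gave -1.24 (adjusted p = 0.017), with 0.078 and 0.089 without vehicle replicates 1 and 3. Sfrp1 gave -0.83 (adjusted p = 0.04). Its p was 0.051 to 0.17 without 160 mg/kg replicate 1, 40 mg/kg replicate 2 or 3, or any vehicle array. At 160 mg/kg no target was called (Hhip -0.57, Sfrp1 -0.07), so a shared fall was not shown. Of 17 targets 4 fell and 0 rose (1 higher and 8 lower adjusted over the list alone, median -0.28, camera adjusted p = 3e-04, adjusted p = 0.043 with an estimated correlation).

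Macrophage markers had more risen members than any other of the 32 lists in resistant tumours. Of 25 markers 21 rose (23 higher and 0 lower adjusted over the list alone, median 1.5, camera adjusted p = 7.5e-27, adjusted p = 0.069 with an estimated correlation). Lysozyme, Lyz2, rose from 554 ± 136 to 2698 ± 1045 (2.14, adjusted p = 0.00013), Slc40a1 to 1304 ± 621 (3.07, adjusted p = 2.2e-06) and Hmox1 to 1005 ± 577 (2.99, adjusted p = 0.00013). Alas2 rose to 307 ± 206 (3.11, adjusted p = 0.00033). Fibroblast and matrix markers had 12 risen and 1 fallen of 28 (22 higher and 2 lower adjusted over the list alone, median 1.04, camera adjusted p = 7e-10, adjusted p = 0.29 with an estimated correlation). Endothelial markers had 2 of 19 risen (7 higher and 1 lower adjusted over the list alone, median 0.65, camera adjusted p = 9.2e-05, adjusted p = 0.35 with an estimated correlation). Pericyte markers had 2 of 13 risen (6 higher adjusted over the list alone, median 0.70, camera adjusted p = 0.00047, adjusted p = 0.34 with an estimated correlation) and neutrophil markers 2 of 10 (6 higher adjusted over the list alone, median 0.94, camera adjusted p = 0.0039, adjusted p = 0.069 with an estimated correlation).

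Drug efflux transporters rose as a list in resistant tumours, with 5 of 17 risen and 0 fallen (7 higher adjusted over the list alone, median 0.41, camera adjusted p = 1.2e-05, adjusted p = 0.043 with an estimated correlation). Abca1 rose from 800 ± 98.7 to 2255 ± 814 (1.37, adjusted p = 0.00044), Abcg1 from 147 ± 40.5 to 351 ± 105 (1.15, adjusted p = 0.002) and Abca3 from 86.4 ± 22.6 to 183 ± 40.6 (0.96, adjusted p = 0.0013), which are known lipid transporters. The multidrug pumps Abcb1a, Abcb1b and Abcg2, chosen after their values were seen, gave 0.31 (adjusted p = 0.61), 0.44 (adjusted p = 0.31) and 0.77 (adjusted p = 0.13). Of 41 measured PI3K and insulin-like growth factor genes 6 rose and 1 fell (6 higher and 1 lower adjusted over the list alone, median 0.04, camera adjusted p = 0.16). The regulatory subunit Pik3r3, chosen after its values were seen, rose from 533 ± 52.3 to 750 ± 118 (0.47, adjusted p = 0.009), and the growth factor gene Igf1, chosen in the same way, rose by 1.96 (adjusted p = 0.00013). Its receptor Igf1r gave -0.09 (adjusted p = 0.72). Macrophage and fibroblast markers were higher in the same tumours.

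Proliferation genes were lower in resistant than in vehicle tumours. Mitosis had 24 of 46 fallen (0 higher and 42 lower adjusted over the list alone, median -0.63, camera adjusted p = 1.1e-24, adjusted p = 0.13 with an estimated correlation). In the resistant arrays macrophage medians ran from 0.37 to 2.07 and fibroblast medians from -0.25 to 1.69. Mad2l1 was at -0.91 (adjusted p = 0.0012) and survivin, Birc5, at -0.74 (adjusted p = 0.0061). DNA replication had 11 of 41 fallen (0 higher and 34 lower adjusted over the list alone, median -0.45, camera adjusted p = 5.7e-17, adjusted p = 0.13 with an estimated correlation). Neuronal differentiation had 5 risen and 1 fallen of 40 (6 higher and 1 lower adjusted over the list alone, median 0.33, camera adjusted p = 0.011, adjusted p = 0.53 with an estimated correlation). Neurod1 went from 305 ± 27.7 to 1277 ± 697 (1.84, adjusted p = 0.00013). Of 32 p53 and apoptosis genes 3 rose and 1 fell (5 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.04, adjusted p = 0.13 with an estimated correlation). Immediate early genes had 4 of 23 risen (4 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.0047, adjusted p = 0.34 with an estimated correlation). Among the falls, Spon2 was at -1.98 (adjusted p = 2.2e-06), but at 160 mg/kg it gave -0.71 (adjusted p = 0.13). Of the 32 lists 17 passed camera in resistant tumours, and 2 of them with an estimated correlation.

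In all 1038 probe sets were higher and 644 lower in resistant tumours. The total was 1105 without 160 mg/kg replicate 3, and 684, 866 and 910 without vehicle replicates 1, 2 and 3. With only these arrays in the fit 243 were called, 242 of them among the 1682, and the adjusted p was 0.051 for Mad2l1, 0.058 for Birc5, 0.13 for Hhip and 0.25 for Sfrp1.

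Resistant tumours at 160 mg/kg were compared with those at 40 mg/kg to ask whether the doses left different tumours. Gli1 gave -0.86 (adjusted p = 0.21, and 0.0057 with an offset of 64 at -0.81), Ptch1 -0.16 (adjusted p = 0.75), Gli2 0.12 (adjusted p = 0.81), Ccnd1 0.12 (adjusted p = 0.81), Mycn 0.33 (adjusted p = 0.23), Smo -0.11 (adjusted p = 0.81, shared probes) and Sufu 0.34 (adjusted p = 0.27). Sfrp1 was 940 ± 435 against 314 ± 163 (SD, n = 3 each, 1.53, adjusted p = 0.0019). Hhip gave 1.34 (adjusted p = 0.042), with 0.15 and 0.21 without 160 mg/kg replicates 1 and 2, and 0.16 and 0.14 without 40 mg/kg replicates 1 and 3. Shisal2b was 800 ± 152 against 58.0 ± 33.7 (3.58, adjusted p = 2.5e-08), Spon2 310 ± 42.3 against 43.6 ± 26.7 (2.53, adjusted p = 2.9e-07) and Sema3e 475 ± 60.2 against 66.0 ± 56.3 (2.98, adjusted p = 7.4e-05). Sptssb, a subunit of the enzyme that starts sphingolipid synthesis, was 2.33 ± 0.851 against 190.0 ± 64.5 (-3.44, adjusted p = 7e-06). The pair of G1 regulators Ccnd3 and Cdk6, of which Ccnd3 was chosen after its values were seen, went apart, with Ccnd3 at 269 ± 28.0 against 1498 ± 512 (-2.36, adjusted p = 1.5e-08) and Cdk6 at 2183 ± 647 against 692 ± 203 (1.64, adjusted p = 1.4e-05).

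Of 32 lists 10 passed camera between the doses and 0 with an estimated correlation. Hypoxia and glycolysis was the list with the smallest camera p, with 7 of 28 higher at 160 mg/kg (13 higher and 0 lower adjusted over the list alone, median 0.60, camera adjusted p = 8.2e-11, adjusted p = 0.54 with an estimated correlation). Neuronal differentiation had 6 higher and 1 lower of 40 (17 higher and 1 lower adjusted over the list alone, median 0.32, camera adjusted p = 1.6e-06, adjusted p = 0.55 with an estimated correlation). Hedgehog targets had 4 higher and 1 lower of 17 (5 higher and 2 lower adjusted over the list alone, camera adjusted p = 0.014, adjusted p = 0.44 with an estimated correlation). Macrophage markers had 1 of 25 lower (0 higher and 1 lower adjusted over the list alone, median -0.60, camera adjusted p = 2.7e-07, adjusted p = 0.55 with an estimated correlation). In all 474 probe sets were higher and 273 lower, and 1186 in total were called without 40 mg/kg replicate 1. With only the resistant arrays in the fit 19 were called, all among the 747. In that fit the adjusted p was 0.34 for Sfrp1, 0.56 for Hhip, 0.17 for Sema3e and 0.08 for Cdk6.

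Resistant tumours were compared with 48 h tumours, which respond to the drug. Hedgehog output was higher in resistant tumours, but without their time since dosing its level under drug was not tested. Gli1 was 899 ± 313 (SD, n = 6) against 12.3 ± 7.37 (SD, n = 3), a change of 4.98 (adjusted p = 1.3e-12), Ptch1 differed by 3.08 (adjusted p = 7.2e-15), Gli2 by 3.09 (adjusted p = 2.3e-15) and Ccnd1 by 3.56 (adjusted p = 2e-16). Mycn differed by 1.39 (adjusted p = 4.2e-10), Hhip by 1.79 (adjusted p = 4.5e-05) and Smo by 0.59 (adjusted p = 5.8e-05, shared probes). Sfrp1 gave -1.04 (adjusted p = 0.001) and 0.074 with each side against its own vehicle set. Sufu gave 0.35 (adjusted p = 0.022), with 0.059 without 160 mg/kg replicate 1 and 0.051, 0.054 and 0.082 without 48 h replicates 1, 3 and 4. Of 17 targets 12 were higher and 2 lower (also 12 and 2 adjusted over the list alone, median 1.12, camera adjusted p = 4.5e-06, adjusted p = 0.0074 with an estimated correlation).

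Proliferation was higher and neuronal differentiation lower in resistant than in 48 h tumours. All 41 DNA replication genes were higher (41 adjusted over the list alone, median 1.71, camera adjusted p = 5.6e-31, adjusted p = 0.062 with an estimated correlation), as were 45 of 46 mitosis genes (45 adjusted over the list alone, median 2.12, camera adjusted p = 5.9e-33, adjusted p = 0.1 with an estimated correlation). Mki67 was at 3624 ± 963 against 573 ± 139 (2.62). Ribosome biogenesis had 29 of 31 higher (30 adjusted over the list alone, camera adjusted p = 3e-17, adjusted p = 0.013 with an estimated correlation). Neuronal differentiation had 30 of 40 lower and 2 higher (3 higher and 30 lower adjusted over the list alone, median -1.37, or -0.81 with each side against its own vehicle set, camera adjusted p = 9.5e-09, adjusted p = 0.21 with an estimated correlation). Slc17a6 was 10.1 ± 10.8 (-5.92, adjusted p = 7.3e-15), Stmn2 20.3 ± 19.5 (-5.39, adjusted p = 7.5e-13) and Chgb 326 ± 383 (-5.20, adjusted p = 5.6e-08), while Nptx1 was 3139 ± 571 (4.60, adjusted p = 1.7e-17).

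Markers of non-tumour cells were lower in resistant than in 48 h tumours, with macrophage markers lower for 24 of 25 (24 adjusted over the list alone, median -1.96, camera adjusted p = 6.3e-13, adjusted p = 0.21 with an estimated correlation), and Cd68 at 448 ± 156 against 3072 ± 848 (-2.78, adjusted p = 7.1e-10). Fibroblast markers had 20 lower and 1 higher of 28 (1 higher and 20 lower adjusted over the list alone, camera adjusted p = 2.2e-05, adjusted p = 0.41 with an estimated correlation). Endothelial markers had 14 lower of 19 (14 adjusted over the list alone, camera adjusted p = 0.0026, adjusted p = 0.41 with an estimated correlation) and interferon genes 24 lower of 27 (24 adjusted over the list alone, camera adjusted p = 5.6e-08, adjusted p = 0.21 with an estimated correlation). Drug efflux transporters had 10 lower and 2 higher of 17 (2 higher and 12 lower adjusted over the list alone, camera adjusted p = 0.0029, adjusted p = 0.16 with an estimated correlation). In all 5778 probe sets were higher and 6485 lower (6447 and 5863 after quantile normalization). With each side set against its own vehicle set, chosen after the data were seen, 6286 were called, 5967 of them called in the same direction in both comparisons.

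The 48 h response was also read in the resistant tumours, using the 4 h vehicle arrays as their control so that no vehicle array enters both sides. The 7211 probe sets that rose at 48 h had a median of 0.22 in resistant tumours, against 1.06 at 48 h itself, and 25.8% of them went the opposite way. The 6203 that fell at 48 h had a median of -0.15, against -0.79 at 48 h itself, and 27.4% of them went the opposite way. In single arrays the median of the risen ran from 0.06 in 160 mg/kg replicate 1 to 0.40 in 160 mg/kg replicate 3, which had the lowest and highest macrophage medians of the resistant arrays (0.37 and 2.07). The correlation across probe sets was 0.57. With each side against its own vehicle set, which also shares no array, it was 0.74, and 18.1% and 18.7% of the risen and fallen went the opposite way. Genes are not independent replicates.

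The 4 h vehicle arrays were compared with the vehicle arrays of no stated time to ask whether the control sets are alike. A small set of genes differed by large amounts. Zfand6 was 324 ± 68.1 (SD, n = 2) against 2247 ± 267 (SD, n = 3), a change of -2.74 (adjusted p = 1.2e-09), and Pus10, a pseudouridine synthase, was 1716 ± 45.2 against 262 ± 22.3 (2.64, adjusted p = 0.00094). Ccdc138 was 31.3 ± 11.9 against 2447 ± 300 (-5.72, adjusted p = 0.0038), with 0.11 without 4 h vehicle replicate 1 and 0.057 without replicate 2. The Hedgehog genes were not called, with Gli1 at -0.17 (adjusted p = 0.95), Ptch1 at -0.28 (adjusted p = 0.73), Gli2 at 0.08 (adjusted p = 0.95), Ccnd1 at 0.25 (adjusted p = 0.74), Mycn at -0.09 (adjusted p = 0.93), Hhip at 0.48 (adjusted p = 0.83), Sfrp1 at 0.04 (adjusted p = 0.99), Smo at -0.08 (adjusted p = 0.93) and Sufu at 0.01 (adjusted p = 1). Of 32 lists 6 passed camera and 0 with an estimated correlation, where adjusted p = 0.87 for each of the 6. Neuronal differentiation had 0 of 40 called (4 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.00018) and cytoplasmic ribosomal proteins 0 of 26 (0 higher and 3 lower adjusted over the list alone, camera adjusted p = 1.3e-07). The other 4 were DNA replication, cholesterol synthesis, macrophage markers and oxidative phosphorylation. In all 11 probe sets were higher and 32 lower, and 2778 had an unadjusted p under 0.05. The total was 15, 17 and 20 without vehicle replicates 1, 2 and 3 and 17 without either 4 h vehicle replicate. With the identifier run as a block it was 3.

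The genome neighbourhood of Gli2 was examined in the GRCm38.p6 gene order, because extra copies of Gli2 are a known route to resistance against Smoothened antagonists and would raise neighbouring genes too. In windows of 11 genes, the median log2 difference from vehicle around Gli2 was -0.20, 0.03 and -0.01 in the 3 resistant tumours at 40 mg/kg and -0.25, 0.07 and -0.14 in the 3 at 160 mg/kg. These medians stood at percentiles 8.1, 50.5 and 48.4, and 3.4, 73.1 and 14.6, of 14743 windows of each array. Gli2 itself lay between -0.79 and -0.09 in the 6 resistant arrays, so no array showed a rise of Gli2 with its window. The neighbours Inhbb and Ralb, chosen after their values were seen, were higher in 5 of the 6 (0.39 to 2.16 and 0.75 to 1.15). Expression cannot count gene copies.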

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

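The tests of the vehicle sets, of non-tumour markers at 48 h and of the spread borrowed from other groups were chosen only after the result was seen, while the tests of macrophage content, of 1 array and of other splits of the arrays were fixed earlier.

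The response at 48 h differed from that at 4 h by a test of the difference itself for 7766 probe sets. The Hedgehog genes fell by more at 48 h, with differences of -2.23 for Gli1, -2.32 for Ptch1, -1.99 for Hhip, -2.41 for Gli2, -0.80 for Mycn, -2.58 for Ccnd1 and -0.97 for Smo, whose probes are shared. The neuronal genes Chgb at 6.06, Stmn2 at 6.03 and Slc17a6 at 6, the macrophage receptor gene Clec7a at 5.17 and the matrix gene Dcn at 5.15 rose by more at 48 h. Larger falls at 48 h were found for S100b at -4.52, the Wnt co-activator Rspo1 at -4.41, the Notch ligand Dll3 at -4.39, Sbspon at -5.02 with shared probes, and Ccdc138 at -5.63, which differs between the vehicle sets. Among the lists, the median difference was -1.20 for Hedgehog targets, -1.96 for DNA replication and S phase, -2.93 for mitosis, 1.06 for drug efflux transporters and -1.06 for ribosome biogenesis. The 4 h and 48 h responses use different vehicle sets, and with all 5 vehicle arrays as control of both the Ccdc138 difference was 0.08.

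The vehicle sets differed at 43 probe sets, and the drug time course lay with the 4 h vehicle. A difference between runs of arrays is argued against, because in the 24 h and 48 h arrays of the run that also holds the vehicle arrays with no stated time at least 76.7% of these probe sets lay on the side of the 4 h vehicle. With the run as a block only 2 of the 43 stayed called, as the median SE went from 0.20 to 0.37 log2, while the median size went from 1.22 to 1.31 and all 43 kept their direction. Scaling is argued against too, since 47 probe sets were called after quantile normalization. Different tumour stocks are a candidate explanation that the values allow, with 82.9% of probe set and array pairs of the 12 treated arrays on the 4 h vehicle side against 23.3% to 44.2% of the probe sets in 5 resistant arrays and 58.1% in 160 mg/kg replicate 2. It stays a hypothesis, since the labels name no stock, and collection time of the vehicle tumours stays open and untested.

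Markers of macrophages, fibroblasts and endothelial cells were higher at 48 h. A lower share of tumour cells alone is not excluded, as rises depend on the starting signal too. The macrophage median exceeded the endothelial median by at least 1.97 (log2) in each of the 3 arrays. That difference had an SD of 0.06. The choice of vehicle set is argued against, since the macrophage median was 3.96 against the 4 h vehicle and 3.50 against the other. An increase of macrophages, or of these transcripts within them, stays open, as does a loss of tumour cells, alone or beside it. No sorted cells or histology are part of the data.

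Resistant tumours at 160 mg/kg differed from those at 40 mg/kg by a test of the difference itself for 747 probe sets. With the per-array macrophage median as a covariate 659 were called, and 532 were called without 160 mg/kg replicate 2. Both fits borrowed spread too, so neither cause is excluded. Spread borrowed from less variable groups fits, since 19 were called with the resistant arrays alone, a fit that also has fewer arrays, and 356 with array weights per group. The median SD of log2 values was 0.269 and 0.257 in the resistant groups against 0.176 to 0.206 in the others, so many of these calls may rest on too small a spread. Whether dose or independent tumour histories underlie the 19 stays open and untested.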

How the results depend on the processing

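The alternatives with matched vehicle sets and with array weights per group were chosen after seeing the data, and the others were planned. No count of called probe sets moved by more than 1.5 times with offsets of 1 or 64, with no filter, with the 60th percentile, with quantile normalization or with the replicate number as a block. That block had little to act on, since deviations of arrays with the same replicate number had a median correlation of 0, with 1 of 70 pairs over 0.1. Of 11794 values of named genes under the alternatives, 11066 kept their direction and side of the threshold, 713 lost the call, 13 gained it and 2 reversed. The reversed values were both of Ccdc138, at 0.08 for the difference between the 48 h and 4 h responses with all 5 vehicle arrays and at -0.76 for resistant against 48 h with matched vehicle sets. Both follow from the control, since Ccdc138 differs between the vehicle sets. Low signals limit what fold changes can show, since the offset of 16 lies near the 40th percentile of the arrays.

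The number of called probe sets depended on how the spread was estimated. Without the trend in eBayes it was 55 at 4 h, 123 for resistant 160 mg/kg, 1089 for both resistant groups, 491 between the doses and 23 between the vehicle sets. With only the arrays compared in the fit it was 187 at 4 h, 1733 at 8 h, 1294 for resistant 40 mg/kg, 8 for resistant 160 mg/kg, 243 for both resistant groups, 19 between the doses and 127 between the vehicle sets, where the fit holds fewer arrays and only the spread of those groups. Array weights per group gave 151 at 4 h, 356 between the doses and 85 between the vehicle sets. With all 5 vehicle arrays as control, which adds control arrays, it was 368 at 4 h, 2366 at 8 h, 2837 for both resistant groups and 12322 for the difference between the 48 h and 4 h responses. With the identifier run as a block it was 25 at 4 h, 545 at 8 h and 3 between the vehicle sets, where each 4 h vehicle array is in another run. Matched vehicle sets gave 6286 for resistant against 48 h. Except where the alternative's construction shows it, the cause was not tested.

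Leaving out 1 array at a time gave 30 to 69 called probe sets at 4 h, 449 to 734 at 8 h, 8340 to 8790 at 24 h, 11665 to 12348 at 48 h, 1468 to 2671 for resistant 40 mg/kg, 45 to 950 for resistant 160 mg/kg, 684 to 2379 for both resistant groups, 532 to 1186 between the doses, 10041 to 12608 for resistant against 48 h, 15 to 20 between the vehicle sets and 5625 to 7544 for the difference between the 48 h and 4 h responses. Where the 4 h vehicle is left with 1 array, that lone array is assumed to vary like the other groups.

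Of the 32 lists, the number past the threshold with an estimated correlation was 1 at 4 h, 2 at 8 h, 4 at 24 h, 2 at 48 h, 1 for resistant 40 mg/kg, 0 for resistant 160 mg/kg, 2 for both resistant groups, 2 for resistant against 48 h, 0 between the doses, 0 between the vehicle sets and 5 for the difference between the 48 h and 4 h responses, against 7, 9, 15, 17, 16, 17, 17, 15, 10, 6 and 17 with the preset correlation. Fry, which asks whether the genes of a list move and does not compare them with other genes, gave 1 at 4 h, 23 at 24 h, 30 at 48 h, 6 for resistant 160 mg/kg, 24 for resistant against 48 h, 2 between the doses and 0 between the vehicle sets.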

Other observations

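Of the tests in this part, the tests of chromosomes and the lists read against the 4 h vehicle were chosen only after the result was seen, and the splits of the arrays were planned.

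Among pathway lists that did not pass camera at 48 h, Hedgehog pathway components had 7 risen and 11 fallen of 27 (7 higher and 11 lower adjusted over the list alone, median -0.22, camera adjusted p = 0.071). Granule neuron progenitor genes had 10 risen and 7 fallen of 23 (10 higher and 7 lower adjusted over the list alone), with a median of 0.08, a mean of -0.07 and a camera direction down (adjusted p = 0.64). PI3K and insulin-like growth factor signalling had 13 risen and 10 fallen of 41 (14 higher and 10 lower adjusted over the list alone, median 0.14, camera adjusted p = 0.42). In that list Pik3r3, chosen after its values were seen, was 611 ± 76.0 (SD, n = 2) in the 4 h vehicle and rose to 1697 ± 46.7 at 8 h (1.45, limma adjusted p = 3.1e-07) and to 1122 ± 127 at 48 h (1.05 against its own vehicle, limma adjusted p = 1.7e-07). Igf1r fell by 0.95 at 48 h (limma adjusted p = 1.3e-06). Receptor tyrosine kinase and MAPK feedback genes had 7 risen and 10 fallen of 29 (7 higher and 10 lower adjusted over the list alone, median -0.23, camera adjusted p = 0.23). Notch signalling had 4 risen and 6 fallen of 20 (4 higher and 6 lower adjusted over the list alone, median -0.10, camera adjusted p = 0.24), Wnt signalling 4 risen and 9 fallen of 28 (4 higher and 9 lower adjusted over the list alone, median -0.11, camera adjusted p = 0.082), p53 and apoptosis genes 11 risen and 6 fallen of 32 (12 higher and 6 lower adjusted over the list alone, median 0.32, camera adjusted p = 0.26) and immediate early genes 7 risen and 3 fallen of 23 (7 higher and 3 lower adjusted over the list alone, median 0.13, camera adjusted p = 0.36).

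Among the marker lists at 48 h, pericyte and smooth muscle markers had 6 of 13 risen (6 adjusted over the list alone, median 1.05, camera adjusted p = 0.051), lymphocyte and natural killer markers 6 of 13 risen (6 adjusted over the list alone, median 0.74, camera adjusted p = 0.12) and astrocyte and glial markers 7 risen and 2 fallen of 20 (7 higher and 2 lower adjusted over the list alone, median 0.36, camera adjusted p = 0.26). Oligodendrocyte and Schwann cell markers had 3 risen and 3 fallen of 13 (3 higher and 5 lower adjusted over the list alone, median -0.36, camera adjusted p = 0.33), and skin markers 1 risen and 1 fallen of 9 (1 higher and 1 lower adjusted over the list alone, median -0.28, camera adjusted p = 0.46). Skeletal muscle had 1 of 20 risen (1 adjusted over the list alone, median 1.26, camera adjusted p = 0.21), with array medians of 1.60, 2.70 and -1.02. None of 5 erythroid markers was called (0 adjusted over the list alone, median -0.08, camera adjusted p = 0.79).

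Called counts were compared with those of other splits of the same arrays. For 24 h the real split gave 10182 and the highest other 1, for 48 h 13414 and 29, for resistant 40 mg/kg 2495 and 6, for resistant 160 mg/kg 355 and 9, and between the doses 747 and 293. In these 5 comparisons 1 of 10 splits, the real one, gave as many, and 10 splits are too few for a share under 0.05. For both resistant groups in 1 group against vehicle, 3 of 84 splits gave as many as the real 1271, so chance can be excluded at 0.05, but the highest other gave 2029. That split sets 160 mg/kg replicate 3 and 40 mg/kg replicates 1 and 2 apart from the other arrays, which points to structure among the resistant arrays. For resistant against 48 h, 1 of 84 splits, the real one with 11951, gave as many, and the highest other gave 3788. The share there is also under 0.05 before adjustment over the comparisons.

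A copy number difference between tumour stocks was tested with the mean expression of each of 20 chromosomes. The 14 arrays with a stated time were compared with the 3 vehicle arrays without. The lowest two-sided exact permutation p was 0.01 over 680 splits, for chromosome 1. Its mean difference was 0.12 log2 (timed arrays 0.04 to 0.20, vehicle -0.05 to 0.07). All others but chromosome 18 rose too (0.01 to 0.09), so part may be array-wide. For chromosome 18 p was 0.019 (timed -0.14 to -0.04, vehicle -0.04 to 0.03). Adjusted over chromosomes both were 0.19 and fail. Between the vehicle sets, where no array had drug, the median was 0.08 for chromosome 1 (camera adjusted p = 0.0021, and 0.12 with an estimated correlation) and -0.08 for chromosome 18 (camera adjusted p = 8.4e-05, and 0.47 with an estimated correlation). Drug alone would not shift the vehicle arrays, but neither chromosome passed with an estimated correlation, so a copy number difference stays open.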
